A study of Mus musculus with 5 samples.

How the data were processed

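Libraries were prepared on the 10x Genomics droplet platform from FACS-sorted OT-I CD8+ T cells, per the labels' protocols. Cell Ranger 2.0.1, Seurat without a version and genome build mm10 are named in the submitters' processing notes, with no role or setting. The deposited values are natural log values: the authors' 3 tables (all time points, 24 h, 72 h) hold the natural log of 1 plus a whole number per gene and cell, as 0 values lay farther than 1e-06 from a whole number after back-transformation. How these whole numbers were made is not given in the sources used here. They are not molecule counts, because their total per cell was nearly constant (coefficient of variation 4.95% over all 13629 cells), so sequencing depth could not be recovered. The 3 tables were adjusted separately: of the values above 0 in either table, 41.9% differed between the table of all time points and that of 24 h in the same cells and genes, and 16.3% for 72 h. The library of each cell was taken from the deposited cell annotation, which gave no cell types.

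The comparisons, gene lists, naming rule and alternatives were fixed before the data were examined, on the assumption that molecule counts would be available. Since the files held adjusted values, no count model, counting interval of a ratio, thinning of cells to equal depth or doublet caller was applied, and doublets were not treated. The adjusted whole number was recovered as exp(value) - 1 and summed per gene and library in the table of all time points (13911 genes), and levels (CPM) are these sums per 1000000 adjusted counts of the library. The 0 h library stood apart in these values, with a variance over mean across cells below 0.5 for 58 genes at 50 CPM or more. Of the values above 0 among 3915 genes found in under 2% of cells, 26.3% equalled 1 at 0 h, against 95.2 to 96.8% in the other libraries. Folds against 0 h therefore carry an unknown bias for such genes, and shares of cells above 0 are not compared with 0 h for them. Genes above the variance limit may be affected too: Gzmb was above 0 in 99.7% of the 0 h cells at a variance over mean of 2.67. Its log2 ratio at 24 h with DCs against 0 h was 2.07, but 0.29 with levels from the mean natural log value.

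There were 4 comparisons: 24 h with DCs against 0 h, 72 h against 24 h with DCs, and DCs with MDSCs against DCs at 24 h and at 72 h. With 1 library per group no test was run and no p-value was computed. Genes at 50 CPM or more in either library were counted when the ratio was 2 or more in either direction. For 35 gene lists, of which 7 were markers of other cell types, the median log2 ratio of members at 10 CPM or more in either library was set against 10000 random lists of the same size, drawn with seed 1 from 20 bins of mean level. Members were called higher or lower at 1.5-fold. A list was called when its percentile was at most 2.5 or at least 97.5, and a list with under 3 measured members got no median. The random lists hold genes drawn independently, while members of a list can vary together, so a call is no measure of significance. Named genes were the 12 with the largest ratio in each direction past 2-fold at 50 CPM or more, the 2 members of each list with the largest ratio in each direction at 20 CPM or more, 20 genes fixed for all libraries, and genes on opposite sides of 2-fold at 24 h and 72 h. Further list members named in the text, H2-Eb1, Cd74, Gm42418 and the myeloid transcripts were chosen after their values were seen. Shares of cells have exact (Clopper-Pearson) 95% intervals, which cover counting error only. The size rule was tested on simulated data made from each MDSC comparison: in both, 100.0% of genes changed 3- or 4-fold passed 2-fold and 0.0% of those changed 1.5-fold or unchanged did. The simulation drew cells around the mean adjusted values, which are not molecule counts, and changed only genes at 2 or more times the minimum level. It held no variation between libraries, so with this many cells its outcome was close to certain. It checks that the rule is computed as stated. It says nothing about counting error in the molecules sequenced or about differences between cultures.

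Cells were clustered on the natural log values (2000 variable genes, 30 principal components, 15 neighbours, Leiden at resolution 1 with seed 1). A cluster was to be assigned to another cell type when 3 or more of that type's markers were among its 10 leading genes. Cells with 3 or more markers of a single other type were counted from markers above 0 in at most 5% of the 0 h cells. Several T cell receptor constant chain and myeloid marker genes of the lists were not among the genes of the table and were not analysed here. Gene positions are from GENCODE release M21 (GRCm38, the assembly of mm10), in which 13461 of the 13911 symbols were found.

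The alternatives were equal weight per cell, ratios centred on their median, a total without ribosomal protein and mitochondrially encoded genes, minimum levels of 10 and 200 CPM, cells with markers of other types left out, the table of the single time point and, for other cell types, a clustering resolution of 0.5. Levels from the mean natural log value, and leaving out genes with a variance over mean below 0.5, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.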

Results

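Single-cell transcriptomes were measured in OT-I CD8+ T cells, mouse T cells that carry a transgenic T cell receptor specific for the ovalbumin peptide SIINFEKL. The cells came from spleen and lymph nodes and were sorted before stimulation (0 h) and after 24 h and 72 h of co-culture. The co-cultures held dendritic cells (DCs) loaded with the peptide, either alone or together with myeloid-derived suppressor cells (MDSCs), immature myeloid cells known for dampening T cell responses. The 5 groups were 1 library each: 2952 cells at 0 h, 1562 cells at 24 h with DCs, 2247 cells at 24 h with DCs and MDSCs, 1926 cells at 72 h with DCs and 4942 cells at 72 h with DCs and MDSCs. Because each group was a single library, no difference below has a replicate check, no test was possible, and every ratio compares 2 libraries.

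The values were whole numbers adjusted for depth, so the number of molecules sequenced per cell is unknown. Levels are given in adjusted CPM, a gene's adjusted counts per 1000000 adjusted counts of its library, written CPM. The adjusted total per cell spanned 13061 to 15988 over all 13629 cells. The median number of genes above 0 per cell was 2210 at 0 h and between 3111 and 3621 in the other 4 libraries.

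The cells carried the expected lineage transcripts in all 5 libraries, with Cd8b1, the CD8 beta chain, at 1871 CPM at 0 h, 548 and 654 at 24 h without and with MDSCs, and 784 and 926 at 72 h. Cd8a stood at 659, 412, 446.5, 424.5 and 625 CPM in the same order. None of 18 clusters of cells had 3 or more markers of another cell type among its 10 leading genes, so no cluster was assigned to another type. The smallest cluster held 43 cells, and scattered cells of another type would not form a cluster. Cells with 3 or more markers from another type's list made up 0.6775% of the cells at 0 h, 2.05% and 1.69% at 24 h without and with MDSCs, and 2.70% and 6.15% at 72 h. Only markers above 0 in at most 5% of the 0 h cells were used. The 0 h share is thus held low by construction and is no baseline for the others. Some transcripts of myeloid cells were found at low level at 24 h with MDSCs. S100a8, an abundant granulocyte transcript, was above 0 in 77 of 2247 cells (3.43%) at 24 h with MDSCs and in 0 of 1562 cells without, and Lyz2, a lysozyme of monocytes and granulocytes, in 52 cells (2.31%) and 0 cells. At 72 h S100a8 was above 0 in 34 of 4942 cells (0.688%) with MDSCs and 0 of 1926 without, and Lyz2 in 7 cells (0.142%) and 1 cell.

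**Figure D1:**
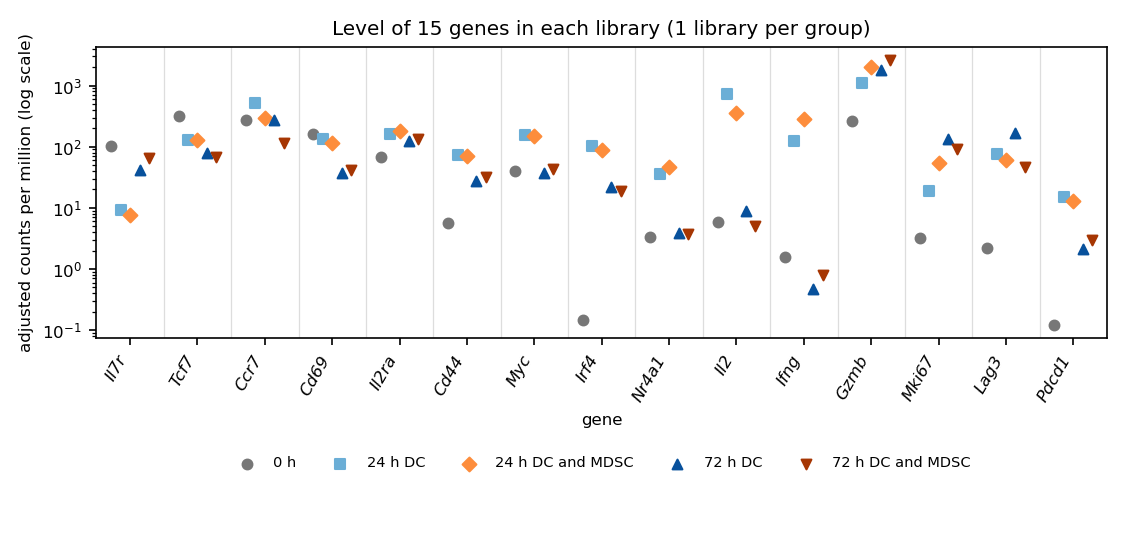
Level of 15 genes in each of the 5 libraries, in adjusted CPM on a log axis, each point standing for 1 library. Il2 stood at 715 CPM at 24 h with DCs and at 355.5 with DCs and MDSCs, and below 10 CPM in the other 3 libraries. Il2ra and Gzmb were above 0 in 94.8% and 99.7% of the 0 h cells, and their 0 h levels may be biased by the depth adjustment.

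The first comparison, 24 h with DCs against 0 h, asked how cells after stimulation without MDSCs differed from cells before it. No library was cultured without peptide-loaded DCs, so an effect of stimulation cannot be told apart from one of 24 h in culture. Of 13 measured cytokine and chemokine genes 11 were at least 1.5-fold higher and 2 lower (median log2 ratio 5.56, and 4.68 from the mean natural log value). Ccl4, a chemokine of activated T cells, was at 1148 against 11.05 CPM, Il2 at 715 against 5.88 (122-fold higher), Xcl1 at 470.5 against 7.23, Ccl3 at 339 against 1.55 and Ifng at 123 against 1.60. The lower members were Ccl5 at 66.2 against 755 CPM and Ltb, lymphotoxin beta, at 121 against 773, but Ccl5 was above 0 in 22.7% and 23.1% of the cells. Irf4, a transcription factor induced by T cell receptor signals, was at 102.5 CPM and was above 0 in 69.5% of the cells, against 3 of 2952 cells at 0 h. Dnph1, a nucleotide hydrolase, was at 56.7 CPM and listed at 0 in every cell at 0 h. Lower at 24 h were Klf2, a factor of T cell quiescence, at 20.5 against 947 CPM (46.2-fold lower), S1pr1, the receptor for exit from lymph nodes and a Klf2 target, at 3.46 against 98.45, the immediate early gene Fos at 2.76 against 161, Cd7 at 3.95 against 215, and the lectin-like receptor gene Klrd1 at 6.67 against 196. With levels from the mean natural log value, which gives less weight to a few cells of very high level, the log2 ratio was 5.10 in place of 6.93 for Il2, 5.81 in place of 6.70 for Ccl4, 4.65 in place of 6.27 for Ifng and -6.54 in place of -5.53 for Klf2. It was -1.32 in place of -3.51 for Ccl5 and -3.56 in place of -2.67 for Ltb.

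The gene lists fixed beforehand followed these genes. Of 22 measured early activation genes, 21 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 2.21 (percentile 100.0 among 10000 random lists matched on mean level); Cd69 was the exception at 135 against 158 CPM. Among 23 naive and quiescence genes 19 were lower and 2 higher (median -2.35, percentile 0.0). Il7r, the IL-7 receptor, was at 9.34 against 102 CPM, while Ccr7 was at 513 against 275 and Bach2 at 55.5 against 18.1. All 36 measured genes of ribosome biogenesis and MYC targets were higher (median 1.68, percentile 100.0), among them Cad, the enzyme of pyrimidine synthesis, at 53.8 against 4.74, and Myc itself was at 156 against 39.96. Of 40 S phase genes 36 were higher (median 2.09, percentile 100.0), led by Cdc6 at 35.7 against 0.266. Cholesterol synthesis genes were higher in 19 of 22 (median 1.92, percentile 99.94), with Idi1 at 69.7 against 4.21. The T cell receptor and CD8 list was lower in 10 of 12 genes (median -1.10, percentile 0.02), with Cd3g at 148 against 1170. Interferon response genes were lower in 18 of 32 and higher in 4 (median -0.91, percentile 0.0); Rtp4 was at 5.88 against 36.4 and Gbp2 at 82.8 against 25.2. Mitochondrially encoded genes were lower in 8 of 12 (median -0.82, percentile 0.28), and mitochondrial genes took 1.57% of all adjusted counts against 2.66%. Inhibitory receptor genes (median 2.48, percentile 99.96), IL-2 and STAT5 targets (1.26, percentile 100.0), and the integrated stress response (1.16, percentile 99.45) also lay above the matched random lists. So did prostaglandin and cAMP responsive genes (1.81, percentile 97.57), but not with the total taken without ribosomal protein and mitochondrial genes (1.10, percentile 78.7). Adhesion and trafficking (-1.76, percentile 0.0), memory associated (-1.27, percentile 0.01), immediate early and dissociation stress (-0.37, percentile 0.48) and oxidative stress genes (-0.16, percentile 1.61) lay below them. The oxidative stress list did not from the mean natural log value (0.17, percentile 5.15), nor without genes of a variance over mean below 0.5 (0.42, percentile 49.4).

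Over the 2742 genes at 50 CPM or more in either library, 871 were at least 2-fold higher and 383 at least 2-fold lower at 24 h, against a median log2 ratio of 0.15 for all genes at that level in both. With the total taken without ribosomal protein and mitochondrial genes, 1271 genes were higher, 746 of them among the 871, and 596 were lower. At 0 h, 58 genes at 50 CPM or more had a variance over mean below 0.5 across cells, against 0 genes in each other library, which is less scatter than counts drawn at random have. Il2ra is such a gene, above 0 in 94.8% of the 0 h cells with a variance over mean of 0.0573, and its 162.5 against 67.9 CPM is given without a fold. For G2 and M phase genes the median was 0.73 (19 of 36 higher, percentile 52.7), so the list was not called. Without genes of such low variance it was called (median 1.82, percentile 100.0), an alternative chosen after seeing the data.

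The second comparison, 72 h against 24 h with DCs, followed the later course without MDSCs. Of 13 cytokine and chemokine genes 10 were at least 1.5-fold lower at 72 h, 1 was higher and 2 were between (median log2 ratio -6.37, and -4.175 from the mean natural log value). Ccl4 was at 0.994 against 1148 CPM, Ccl3 at 0.24 against 339, Ifng at 0.48 against 123, Xcl1 at 2.57 against 470.5 and Il2 at 8.98 against 715 (79.6-fold lower). Lta was at 33.8 against 223 and Ltb, the higher member, at 566 against 121. Higher at 72 h were Bnip3, a mitophagy receptor induced by hypoxia, at 347 against 2.92 CPM (119-fold higher), the metallothioneins Mt1 (1377 against 11.5) and Mt2 (635 against 5.31), the cyclin Ccnb2 (178 against 1.73), and Aldoc, a glycolytic aldolase (168 against 0.247). H2-Ab1, an MHC class II chain, was above 0 in 89.1% of the cells at 72 h and in 0.640% at 24 h. With levels from the mean natural log value the log2 ratio was -4.175 in place of -6.31 for Il2, -5.96 in place of -8.00 for Ifng, -8.98 in place of -10.17 for Ccl4, -9.15 in place of -10.46 for Ccl3 and -6.45 in place of -7.515 for Xcl1. For Ltb it was 3.03 in place of 2.22.

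Of 18 hypoxia and HIF target genes 17 were higher and 0 lower (median 2.75, percentile 100.0), and of 19 glycolysis genes 17 were higher and 1 lower (median 1.78, percentile 100.0). Slc16a3, a lactate exporter, was at 220 against 2.30 CPM and Slc2a3, a glucose transporter, at 197 against 8.11. G2 and M phase genes were higher in 48 of 54 and lower in 0 (median 1.74, percentile 100.0), whereas 27 of 42 S phase genes were within 1.5-fold (median -0.33, percentile 35.7). All 36 ribosome biogenesis genes were lower (median -2.07, percentile 0.0), with the spermidine synthase Srm at 71.3 against 855. Early activation genes were lower in 15 of 22 (median -1.63, percentile 0.0), for example Nfkbid at 3.88 against 86.8, and Tnfrsf18 was at 455 against 229. Adhesion and trafficking genes were higher in 19 of 25 (median 1.86, percentile 100.0), including Anxa2 at 566 against 14.7, and 19 of 30 interferon response genes were higher (median 1.04, percentile 100.0), including Phf11b at 100.2 against 5.19. Cytotoxic and effector genes were higher in 10 of 17 (median 0.81, percentile 99.89), with Klrd1 at 76.7 against 6.67; Gzmb, granzyme B, was at 1796 against 1118 (log2 ratio 0.68, and 1.95 from the mean natural log value) and Prf1, perforin, at 1.03 against 0.370. Cholesterol synthesis genes (median 1.21, percentile 100.0), inhibitory receptors (0.93, percentile 98.86), the T cell receptor and CD8 list (0.59, percentile 98.98) and naive and quiescence genes (0.36, percentile 98.44) also lay above the matched random lists. Inhibitory receptors were split, with 6 of 11 higher and 5 lower: Lag3 was at 166 against 75.9 CPM and Pdcd1 at 2.13 against 14.8. Naive and quiescence genes were higher in 8 of 21 and lower in 6. Arginine, polyamine and tryptophan metabolism (-1.01, percentile 0.53) and TGF-beta responsive genes (-1.25, percentile 0.18) lay below them. The latter did not with the total taken without ribosomal protein and mitochondrial genes (-0.59, percentile 17.6). Of 2931 genes, 478 were at least 2-fold higher and 696 at least 2-fold lower, against a median log2 ratio of -0.14.

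The third comparison, 24 h with DCs and MDSCs against 24 h with DCs, asked what MDSCs did early in the response. Few genes stood apart. Mki67, a proliferation marker, was 2.89-fold higher with MDSCs (55.1 against 19.05 CPM), together with the histone genes Hist1h2ap (131 against 26.5) and Hist1h1e (56.95 against 26.6) and the mitotic genes Cdca3 (57.2 against 20.2), Ube2c (64.8 against 25.3), Birc5 (192 against 87.6) and Aurkb (57.7 against 26.99). Ifng was 2.3-fold higher (283 against 123) and Eif4ebp1, a repressor of cap-dependent translation, was at 354 against 128. Serpine2, a secreted protease inhibitor, was 6.42-fold lower (19.9 against 128), Cdkn1a, the cell cycle inhibitor p21, 2.53-fold lower (28.9 against 73.2), S100a11 at 41.8 against 103 and Il2 2.01-fold lower (355.5 against 715). Gzmb was at 1987 against 1118 CPM (log2 ratio 0.83, and 1.61 from the mean natural log value), and Irf4, Myc, Cd69, Il2ra, Cd44, Pdcd1, Lag3 and Nr4a1 had log2 ratios between -0.31 and 0.35.

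G2 and M phase genes were higher in 29 of 45 and lower in 1 (median 0.76 against 0.08 for matched random lists, percentile 100.0). Glycolysis genes were higher in 4 of 17 (median 0.46, percentile 100.0), with Tpi1 at 640.0 against 354, and hypoxia and HIF targets in 3 of 11 (median 0.42, percentile 100.0), with Egln3 at 33.1 against 15.8. Genes of the integrated stress response were higher in 9 of 33 (median 0.42, percentile 100.0), led by Pck2 at 26.04 against 8.27 and Asns at 28.7 against 15.3. Lists below the matched random lists included those of the interferon response (5 of 21 genes lower, median -0.28, percentile 0.0; Gbp2 at 41.8 against 82.8), inhibitory receptors (3 of 10, median -0.31, percentile 0.02; Btla at 11.7 against 20.6), naive and quiescence (3 of 18, median -0.19, percentile 0.0; Ccr7 at 298 against 513) and p53 targets (5 of 15, median -0.09, percentile 0.39; Phlda3 at 8.50 against 36.75). In single cells the median sum over the p53 targets was 30 adjusted counts in both 24 h libraries, with 47.98% of the cells with MDSCs below the median of those without, while the 95th percentile was 42 with MDSCs and 60 without. Early activation genes (median -0.12, percentile 0.0), cytokines and chemokines (-0.12, percentile 0.03) and TGF-beta responsive genes (-0.21, percentile 0.03) also lay below the matched random lists. Most of their members were within 1.5-fold, 20 of 22, 9 of 13 and 9 of 10 in this order. Of the others, early activation had 1 higher and 1 lower and cytokines 2 and 2. From the mean natural log value the cytokine median was 0.19 (percentile 81.5). Apoptosis regulators (-0.039, percentile 0.85), IL-2 and STAT5 targets (0.0054, percentile 0.03) and oxidative phosphorylation (0.059, percentile 1.39) lay below their random lists too. Nearly all members of these lists were within 1.5-fold: 18 of 19, 19 of 21 and 45 of 45 in this order. The other 2 IL-2 and STAT5 targets were higher. With ratios centred on their median, the IL-2 and STAT5 list had a median of -0.15 and oxidative phosphorylation one of -0.10. S phase genes (0.31, percentile 100.0), mitochondrially encoded genes (0.27, percentile 99.91) and oxidative stress genes (0.21, percentile 98.75) lay above the matched random lists. Here too most members were within 1.5-fold, 39 of 42, 12 of 12 and 19 of 21. The share of cells with Il2 above 0 was 43.6% (exact 95% interval 41.55 to 45.7%) with MDSCs and 52.4% (49.9 to 54.9%) without. For Ifng the shares were 28.5% (26.6 to 30.4%) and 15.8% (14.0 to 17.7%), and for Mki67 45.97% (43.9 to 48.1%) and 19.0% (17.1 to 21.05%); these intervals cover counting error only. With the 24 h cells ranked by summed S, G2 and M phase counts and parted into 3 sets of nearly equal number, from the lowest to the highest, the log2 ratio of Il2 was -1.36, 0.07 and 0.21. In the same order that of Cdkn1a was -1.68, 0.12 and -0.39, that of Serpine2 was -2.95, -1.45 and -0.96, and the median of the p53 targets was -0.38, 0.05 and 0.03. Beside the mitotic genes, ribosomal RNA-like transcripts were also higher with MDSCs, with Gm26917 at 336 against 149.7, Gm42418 at 321 against 158 and AY036118 at 111 against 38.8 CPM, and ribosomal protein genes took 33.7% of adjusted counts against 38.8%. Of 2717 genes, 14 were at least 2-fold higher and 4 at least 2-fold lower, against a median log2 ratio of 0.16; with that median set to 0 the counts were 8 and 5. In the table adjusted for 24 h alone 9 genes were higher. With levels from the mean natural log value 20 genes were higher and 2 lower, and 7 of the 14 and 2 of the 4 were among them.

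The fourth comparison, 72 h with DCs and MDSCs against 72 h with DCs, asked the same at the later time. Hypoxia-inducible and glycolytic transcripts were far lower with MDSCs. Ndrg1 was 19.7-fold lower (8.70 against 171 CPM), Slc2a3 12.9-fold lower (15.3 against 197), Slc16a3 8.97-fold lower (24.55 against 220), and Mgarp, Gbe1, Ankrd37, Hilpda and Ero1l had log2 ratios between -4.83 and -3.19. H2-Ab1 was 15.96-fold lower (15.97 against 255), Selenbp1 12.7-fold lower (14.8 against 187) and Klf2 at 22.7 against 140. Higher with MDSCs were Serpine2, 13.4-fold (168 against 12.5 CPM), Phlda3, 7.04-fold (87.6 against 12.45), S100a6, 7.6-fold (2632 against 346), Cox6b2, a subunit of cytochrome c oxidase (295 against 17.4), the lactate dehydrogenase Ldhb (80.1 against 12.3) and Ccng1, a p53 target (272 against 62.9).

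All 19 glycolysis genes were lower with MDSCs (median -1.26, percentile 0.0), including Gapdh at 3693 against 7827, Ldha at 1783 against 3671 and Pkm at 1023 against 2354 CPM. Of 18 hypoxia and HIF targets 16 were lower and 0 higher (median -1.78, percentile 0.0), with Bnip3 at 46.4 against 347 and P4ha2 at 2.45 against 43.96, whereas Hif1a, the oxygen-regulated factor itself, was at 82.25 against 87.7. In single cells, 99.96% of those with MDSCs had a summed adjusted count over the hypoxia and HIF genes below the median of the cells without, 20 against 68 at the medians. For p53 targets 17 of 18 were higher and 0 lower (median 1.21, percentile 100.0), including Cdkn1a at 395 against 177, Bax at 607 against 278, Rps27l at 2141 against 776, Mdm2 at 53.1 against 26.2 and Perp at 33.9 against 3.36. Ribosome biogenesis genes were higher in 16 of 33 (median 0.58, percentile 100.0) and oxidative phosphorylation genes had a median of 0.24 (percentile 99.99), with Cycs, cytochrome c, at 586 against 353.5. Inhibitory receptor genes were lower in 4 of 8 and higher in 2 (median -0.66, percentile 0.43). With the total taken without ribosomal protein and mitochondrial genes the list was not called (median -0.01, percentile 49.5). That total raises all levels, so more genes can pass the minimum level. Lag3 was at 46.6 against 166 and Ctla4 at 48.8 against 145.5 CPM. Early activation genes were lower in 6 of 16 (median -0.33, percentile 1.37), with Tnfrsf9 at 117 against 257, and naive and quiescence genes in 10 of 22 (median -0.40, percentile 0.23), with Ccr7 at 114 against 277.5 but Il7r at 64.1 against 41.4. Cytotoxic and effector genes were lower in 8 of 17 and higher in 3 (median -0.41, percentile 0.715). Gzmb was at 2592 against 1796, Gzma at 77.95 against 181 and Mki67 at 90.3 against 135; G2 and M phase genes had a median of -0.22 (percentile 0.48), and 45 of 54 were within 1.5-fold.

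Cells that carried 3 or more markers from another type's list made up 6.15% (exact 95% interval 5.50 to 6.86%) of the cells with MDSCs and 2.70% (2.02 to 3.53%) of those without, and nearly all of them, 292 of 304 and 52 of 52, did so by the dendritic cell list. Genes of that list were found in many cells: H2-Ab1 in 19.95% with MDSCs and 89.1% without, and H2-Eb1 in 25.8% and 1.61%. These shares of cells therefore do not measure how many cells were of another type. Of 7 measured genes of that list 4 were higher and 1 lower with MDSCs (median 0.69, percentile 99.93), but with levels from the mean natural log value the median was 0.094 (percentile 66.2). Of the ribosomal RNA-like transcripts, Gm26917 was at 196 against 87.0 CPM, Gm42418 at 238 against 194 and AY036118 at 65.0 against 40.8. Of 2424 genes, 50 were at least 2-fold higher and 138 at least 2-fold lower, against a median log2 ratio of 0.04. With the total taken without ribosomal protein and mitochondrial genes, 87 genes were higher and 180 lower.

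**Figure D2:**
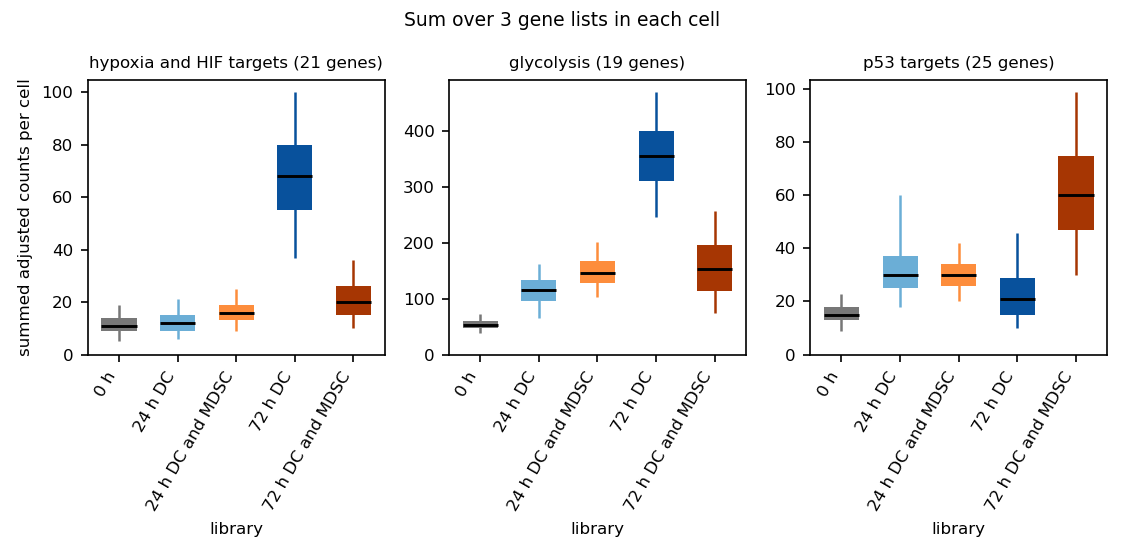
Adjusted counts per cell summed over 3 gene lists (hypoxia and HIF targets, glycolysis, p53 targets) in the 5 libraries. Black lines are medians over cells, boxes the middle 50% of cells and thin lines the range from the 5th to the 95th percentile; at 72 h the median glycolysis sum was 355 with DCs and 153 with DCs and MDSCs, and the median p53 target sum was 21 and 60.

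Set side by side, the MDSC ratios of the 2 times shared no library and showed little relation across genes, with a Pearson r of -0.10 and a Spearman rho of -0.08 over 1963 genes, which are not independent replicates. Of these genes, 2 stood at least 2-fold on opposite sides. With levels from the mean natural log value Serpine2 alone did, and with the total taken without ribosomal protein and mitochondrial genes 4 did. The number depends on the minimum level, with 14 genes at 10 CPM and 0 at 200 CPM. Serpine2 (chromosome 1, 79794197 to 79861180, protein-coding, mm10) had a log2 ratio of -2.68 at 24 h and 3.75 at 72 h, and Cdkn1a (chromosome 17, 29090976 to 29100727, protein-coding, mm10) of -1.34 and 1.16. Among the gene lists, 4 had medians of opposite sign that lay outside the central 95% of random lists at both times: hypoxia and HIF targets (0.42 and -1.78), glycolysis (0.46 and -1.26), G2 and M phase genes (0.76 and -0.22) and p53 targets (-0.09 and 1.21, the former without a difference in the median sum per cell). Most lists with a median lay outside the central 95% at each of these times, so lying outside it does not single out a list. The medians of the 2 times were taken over different measured members. These were 11 and 18, 17 and 19, 45 and 54, and 15 and 18, in the order of the 4 lists named. The difference between the times was not tested.

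**Figure D3:**
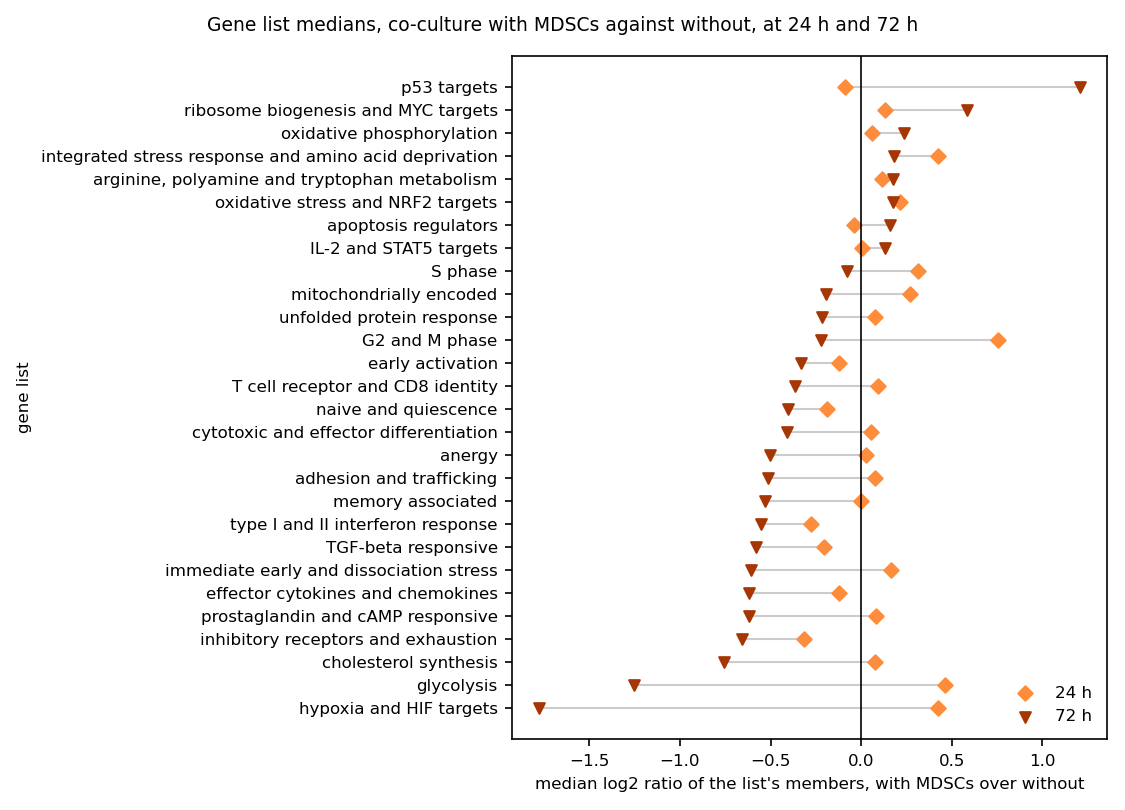
Median log2 ratio of each gene list's members, co-culture with MDSCs over co-culture without, at 24 h (diamonds) and at 72 h (triangles), with 1 row per list and a line joining its 2 medians. Hypoxia and HIF targets lay at 0.42 and -1.78, and p53 targets at -0.09 and 1.21.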

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

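The following results stood on opposite sides with MDSCs at 24 h and at 72 h, with 1 library per group, and the difference between the times was not tested. The tests on the adjustment, on cells of another type, on differences between cultures and on cycling cells were chosen after the result was seen.

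For Serpine2 the log2 ratio with MDSCs was 6.43 higher at 72 h than at 24 h, and for Cdkn1a it was 2.495 higher. With levels from the mean natural log value Cdkn1a no longer stood at least 2-fold on opposite sides. With the 24 h cells ranked by summed S, G2 and M phase counts and parted into 3 sets of nearly equal number, the 24 h ratio of Serpine2 from the lowest set to the highest was -2.95, -1.45 and -0.96. That of Cdkn1a was -1.68, 0.12 and -0.39, so it was 2-fold lower in the lowest set alone. The list medians differed by 1.30 for p53 targets, -2.20 for hypoxia and HIF targets, -1.72 for glycolysis and -0.98 for G2 and M phase genes, each as 72 h minus 24 h. These medians cover different measured members at 24 h and 72 h: 15 and 18, 11 and 18, 17 and 19, and 45 and 54 in this order, so part of a difference can come from the members.

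The lower hypoxia and HIF targets at 72 h could come from the adjustment of all time points together, but in the table adjusted for 72 h alone the list's median log2 ratio was -1.77. Cells of another type in 1 of the libraries would move only their own share of the cells, and 99.96% of the cells with MDSCs lay below the median of the cells without in their sum over the list. Leaving out cells with markers of other types gave list medians within 1.5-fold of the main ones. This adds little, as at most 6.15% of a library's cells were left out. The markers also do not measure how many cells were of another type. A difference between cultures or libraries other than the MDSCs, such as cell density or oxygen in the well, cannot be told apart from an effect of MDSCs with 1 library per group. An effect of the MDSCs therefore stays open as a hypothesis beside it.

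The higher p53 targets at 72 h could likewise come from the joint adjustment, but in the table adjusted for 72 h alone the list's median log2 ratio was 1.202. A different share of cycling cells is argued against at 72 h: with the cells ranked by summed S, G2 and M phase counts and parted into 3 sets of nearly equal number, the medians were 1.31, 1.135 and 1.34 from the lowest set to the highest. At 24 h the medians were -0.376, 0.05 and 0.03, so the lower side was seen in the lowest set alone, where the median cycle count was 64 without and 74 with MDSCs, and a different share of cycling cells stays open for it. The median sum over the list per cell was 30 in both 24 h libraries, and the 95th percentile 60 without and 42 with MDSCs. A difference between cultures or libraries stays open at both times, with 1 library per group.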

How the results depend on the processing

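The alternatives that take levels from the mean natural log value, and that leave out genes of low variance, were chosen after seeing the data. With 1 library per group there was no spread between replicates, so a log2 value was taken as moved at 1.5-fold, a count of genes at 1.5 times and a share of cells outside its exact 95% interval. Of 754 list medians under an alternative 735 stayed within this limit, 11 moved and 8 reversed. The 8 all belonged to lists called in the main analysis. Other medians near 0 changed sign under centring without being counted, such as anergy with MDSCs at 24 h (0.03 against a centre of 0.16). All list medians with MDSCs at 24 h were smaller than 1.5-fold, except that of G2 and M phase genes. Staying within the limit says little there. Of 3274 values of named genes 3246 stayed and 28 moved, 26 of them with levels from the mean log. The 85 shares of cells above 0 were recomputed without cells with markers of other types alone, and stayed within their intervals. Molecule counts were not recoverable, so counting intervals of ratios, cells thinned to equal depth, a doublet caller and limits on molecules per cell were not run. No paired analysis was possible because each group is 1 library.

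Centring the ratios left 8 genes at least 2-fold higher with MDSCs at 24 h. With the total taken without ribosomal protein and mitochondrial genes, 1271 genes were higher and 596 lower at 24 h than at 0 h. With MDSCs at 72 h, 87 were higher and 180 lower. By that total 4 genes lay on opposite sides at the 2 times (Serpine2, Phlda3, Mt1, Cdkn1a). It raises all levels, so more genes can pass the minimum of 50 CPM. In the main levels Phlda3 (log2 ratios -2.11 and 2.815) and Mt1 (1.60 and -1.90) already lay on opposite sides, but were below 50 CPM at 24 h. The table of the single time point gave 9 genes higher with MDSCs at 24 h. Levels from the mean log gave 2 genes lower with MDSCs at 24 h and 1 gene, Serpine2, on opposite sides. Apart from the effect of the minimum level, the cause was not tested.

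By construction, a minimum of 10 CPM admitted more genes: 2865 higher and 744 lower at 24 h than at 0 h, 1137 and 1528 at 72 h than at 24 h, 36 and 20 with MDSCs at 24 h, 139 and 370 with MDSCs at 72 h, and 14 on opposite sides. A minimum of 200 CPM gave 157 and 146, 142 and 155, 4 and 1, 9 and 40, and 0 in the same order. Counting cells with 3 or more markers of another type in place of clusters gave 0.6775%, 2.05%, 1.69%, 2.70% and 6.15% of the cells at 0 h, at 24 h without and with MDSCs, and at 72 h without and with MDSCs. The markers used were those rare at 0 h, which holds the 0 h share low.

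These list medians, all of called lists, were counted as reversed. With MDSCs at 24 h, oxidative phosphorylation had -0.10 with centring and -0.052 without ribosomal protein and mitochondrial genes, and IL-2 and STAT5 targets -0.15, -0.11 and, in the table of 24 h alone, -0.0093. The cytokine list had 0.19 with levels from the mean log, against -0.12. For oxidative stress and NRF2 targets at 24 h against 0 h the reversed median was 0.17 with levels from the mean log and 0.42 without genes of low variance. The cause was not tested.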

Other observations

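The tests in this part were chosen after the result was seen, except the test of Il2 by cell cycle counts.

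Further gene lists were called with MDSCs at 72 h, as most lists with a median were. Cholesterol synthesis genes were at least 1.5-fold lower in 16 of 23 and higher in 0 (median log2 ratio -0.76, percentile 0.0 of matched random lists), for example Insig1 at 13.2 against 32.3 CPM, while at 24 h 22 of 22 were within 1.5-fold (median 0.08). Interferon response genes were lower in 13 of 29 (median -0.55, percentile 0.0), with Iigp1 at 9.29 against 40.05 and Gbp2 at 39.1 against 122, but Ifi35 was at 115 against 51.0 and Bst2 at 344 against 213. Adhesion and trafficking genes were lower in 11 of 25 (median -0.51, percentile 0.0), where Lgals3 was at 30.3 against 162 and, on the other side, S100a4 at 128 against 13.4 (log2 ratio 3.26, and 2.52 from the mean natural log value). Of the oxidative stress genes, Mt1 was at 368 against 1377 and Mt2 at 260 against 635, while the ferritin light chain Ftl1 was at 2710 against 1530 and Prdx1 at 814 against 462. Ass1, which makes argininosuccinate from citrulline, was at 130 against 57.1 CPM at 72 h and at 30.04 against 20.5 at 24 h. Genes of the immediate early and dissociation stress list, which also respond to handling of cells, were lower in 8 of 15 and higher in 0 (median -0.61, percentile 0.03). Memory associated genes (median -0.53, percentile 0.08), anergy genes (-0.50, percentile 0.37), and the T cell receptor and CD8 list (-0.37, percentile 0.23) also lay below the matched random lists. So did TGF-beta responsive genes (-0.58, percentile 2.25), prostaglandin and cAMP responsive genes (-0.62, percentile 2.49) and 4 measured cytokine genes (-0.62, percentile 1.2). The integrated stress response lay above them (0.18, percentile 99.06), but 5 of its 34 genes were higher, 5 lower and 24 within 1.5-fold.

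MHC class II chains did not go together in these libraries. H2-Ab1 was above 0 in 89.1% of the cells at 72 h with DCs and in 19.95% with DCs and MDSCs. H2-Eb1 went the other way, at 1.61% and 25.8%. H2-Aa, the partner chain of H2-Ab1, was above 0 in 0.571% and 0.425%, and Cd74 in 3.74% and 12.9%.

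At 0 h, 27 of 121 early activation, S phase and G2 and M phase genes were above 0 in 90% or more of the 0 h cells. Filling in of values by the depth adjustment may account for this: of the values above 0 among rarely found genes, 26.3% equalled 1 at 0 h, against 95% or more in each other library, and the value 2 made up 70.3%. RNA free in the suspension stays open: the median variance over mean of the 27 genes was 0.536 at 0 h, against 1.36 to 2.135 in the other libraries, but after the adjustment this scatter says nothing of the molecules counted. No biological explanation was tested.

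A hypothesis for the lower Il2 and higher Ifng at 24 h with MDSCs is that more cells were further in the cell cycle. With the cells ranked by S, G2 and M phase counts and parted into 3 sets of nearly equal number, Il2 should then differ little within a set. The log2 ratio was -1.36 in the lowest set (425.5 against 1092 CPM), 0.072 in the middle and 0.21 in the highest, so the 2 libraries differed by more than 1.5-fold in the lowest set alone. The test, which covered Il2 alone, stays open, because within that set the median cell cycle count was 74 with MDSCs and 64 without. The ratio of Ifng was 1.73, 1.78 and 0.15 from the lowest to the highest set, against 1.205 over all cells. In the middle set Ifng was at 315 against 92.0 CPM, at median cycle counts of 124 and 117. For Ifng in the middle set these values argue against the hypothesis, since even the highest set without MDSCs was at 190 CPM. The lowest set leaves it open for Ifng too, because its cycle counts differed. No prediction was made for Ifng, and each group is 1 library. Ifng was above 0 in 15.8% of the 24 h cells without MDSCs, so its levels in a set rest on a minority of cells. The ratio of Gzmb was 1.255, 0.75 and 0.705.

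Of the 18 clusters, 1 with Il2, Marcksl1, Cd200 and Ccl4 among its leading genes held 605 of the 1562 cells at 24 h with DCs and 30 of the 2247 cells with DCs and MDSCs. At a resolution of 0.5 the cluster led by these genes held 514 and 85 cells, and at the main resolution a smaller cluster led by Il2 and Ccl4 held 13 and 30. Another cluster, led by Ccl9, Ifng, Ccl5, Fcer1g, Klra9 and Klre1, held 75, 22, 53, 3 and 3 cells of the 5 libraries in order of time; it had 2 markers of NK cells among its 10 leading genes and was left unnamed.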
